A study of Homo sapiens with 6 samples.

How the data were processed

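The series compared AGS gastric adenocarcinoma cells transfected with CTNNB1 siRNA and with non-targeting control siRNA (Dharmacon, per the labels' protocols). Total RNA was extracted with Trizol 48 hours after transfection, and 500 ng per sample was converted to biotin-labelled sense cDNA with the Ambion WT Expression kit, per the labels' protocols. The deposited values are log2 expression per transcript cluster on the Affymetrix Human Gene 1.0 ST array, made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA subtracts background, normalises the arrays to a common distribution of probe intensities and summarises the probes of a cluster, so a change shared by all transcripts would not be visible, and differences of dim clusters are compressed towards 0. The settings of the summarisation, the genome build and the annotation are not given in the sources used here, nor are the siRNA sequences or the number of siRNAs in the reagent. The log2 scale was taken from the range of the deposited values, which run from about 1 to 14 with array medians of 5.38 to 5.46.

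Arrays were grouped by the siRNA in their labels, 3 per group. The titles call them biological replicates; nothing says that they came from separate passages or days, so the p-values measure the spread between these samples. No pair of arrays shared more than 19 identical values, so none was counted as a copy of another.

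Of the 33297 transcript clusters in the table, the platform's annotation paired 19460 with exactly 1 gene symbol, and these were tested. A further 1754 were paired with several symbols and 12083 were not listed with a gene, and both kinds were left out of the gene tests. Symbols were updated through the gene identifiers of the RefSeq gene table for GRCh38.p14 for 19429 of the tested clusters, and 31 kept the platform's symbol. No coordinate of that assembly is given. The tested clusters covered 18417 genes, of which 769 had more than 1 cluster, and the cluster with the highest mean over all 6 arrays then stood for the gene. Of 985 symbols in the gene lists, 902 had a tested cluster. Of the 14 genes to be named whatever their result, 11 had a tested cluster; the others, TCF7 among them, are not analysed here.

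The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the log2 values, 2-sided, with Benjamini-Hochberg adjustment over the tested clusters and a threshold of 0.05, without a filter on dim clusters, without weights and without a block. Differences are CTNNB1 siRNA minus control siRNA. Gene lists were tested with camera in limma, which compares a list with all other genes, with a preset correlation between genes of 0.01, on 1 cluster per gene and adjusted over the 33 lists, and also with camera's estimated correlation and with fry. The lists were fixed before the data were examined: Wnt target genes, Wnt pathway components, adherens junction and desmosome, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, p53 targets, apoptosis regulators, interferon response, NF-kB and inflammatory genes, MHC class I and antigen presentation, ERK feedback and immediate early genes, YAP/TEAD targets, TGF-beta and BMP targets, epithelial to mesenchymal transition, gastric and intestinal differentiation, stem cell and progenitor markers, the Notch pathway, unfolded protein and integrated stress response, heat shock and proteotoxic stress, NRF2 and oxidative stress, cholesterol synthesis, fatty acid and lipid synthesis, glycolysis and hypoxia, oxidative phosphorylation, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, small RNA machinery, membrane traffic and lysosome, integrins and extracellular matrix, immune cell markers, fibroblast and endothelial markers, and reference genes.

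The rule for genes named in the text was fixed at the same time. It names CTNNB1 first, then up to 15 rises and 15 falls with the largest log2 difference among genes past the threshold whose groups do not overlap and whose higher group mean reaches the median of all tested clusters, then from each list up to 4 members past the threshold or otherwise up to 2 with the smallest p, and 14 fixed genes, mostly of the Wnt pathway, whatever their result. Non-coding, olfactory receptor, uncharacterised and similar symbols were excluded from the first of these parts. Not every gene that the rule allows is named. Any gene outside the rule is said to have been chosen after its values were seen.

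The procedure was tested on simulated data with the spread of these arrays: over 5 runs of 19460 clusters, with 100 changed by each size, 51.6% of genes changed by 1 on the log2 scale and 90.2% of those changed by 2 were found, and 4.19% of calls were false. With the spread of the arrays without CTNNB1 siRNA replicate 1, 66.6% and 93.8% were found and 5.09% were false. In 50 simulated sets of 33 independent genes, the size of the differentiation list, camera gave p under 0.05 in 2% without a shift and in 100% with a shift of 0.3. With the estimated correlation the share with the shift was 100% as well. Every gene of a simulated set was shifted. The real list had an estimated correlation of 0.0781, a median difference of 0.13 and 14 members lower, so these shares need not hold for it.

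The alternatives were quantile normalisation between arrays, centring on array medians, leaving out clusters below the 40th percentile of mean expression, testing all clusters of the table, an intensity trend with robust eBayes, array quality weights, the replicate number as a block, each array left out in turn, 1 cluster per gene, an adjusted p threshold of 0.01, a fold minimum of 1.5, treat in limma against a fold of 1.2, and, for lists, the estimated correlation, fry and the mean of a gene's clusters. Leaving out the arrays numbered 1 of both groups together, the estimated correlation with each array left out, and each array left out for the mucin and CEACAM families, were added after the data were seen.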

Results

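Gene expression was measured in AGS cells, a human gastric adenocarcinoma line, 48 hours after transfection with siRNA against CTNNB1, the gene of beta-catenin, or with a non-targeting control siRNA. Each group held 3 arrays, which the sample titles call biological replicates, so 6 Affymetrix Human Gene 1.0 ST arrays entered the comparison. The median log2 expression of an array lay between 5.38 and 5.46 over the 33297 transcript clusters in the table. CTNNB1 siRNA replicate 1 stood apart from the other arrays: its Pearson correlation with each of them, taken across transcript clusters, was 0.963 to 0.967, against 0.984 to 0.993 among the remaining pairs. The number of arrays limited the precision of every value given here.

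The first question was how far CTNNB1 itself was silenced. CTNNB1 (transcript cluster 8079021) averaged 11.81 ± 0.091 (SD, n = 3) on the log2 scale in control siRNA cells and 10.54 ± 0.26 (SD, n = 3) in CTNNB1 siRNA cells. This log2 difference of -1.27 (SE 0.17) left 41.6% of the control level, with a 95% confidence interval of 31.8% to 54.2%. Each CTNNB1 siRNA array (10.27, 10.78 and 10.58 for replicates 1 to 3) lay below each control array (11.92, 11.76 and 11.75), so the target matched the group label on all 6 arrays. In limma the adjusted p of CTNNB1 was 0.232 over all 19460 transcript clusters tested, the fifth smallest p among them, and it was 0.000775 when adjusted over the 12 Wnt pathway and adhesion genes fixed beforehand and tested. These 12 include CTNNB1 itself. They were fixed for naming, and no adjustment over them was planned. The 2-sided exact permutation p of 3 arrays against 3 cannot fall below 0.1, the value that this complete separation gives.

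**Figure D1:**
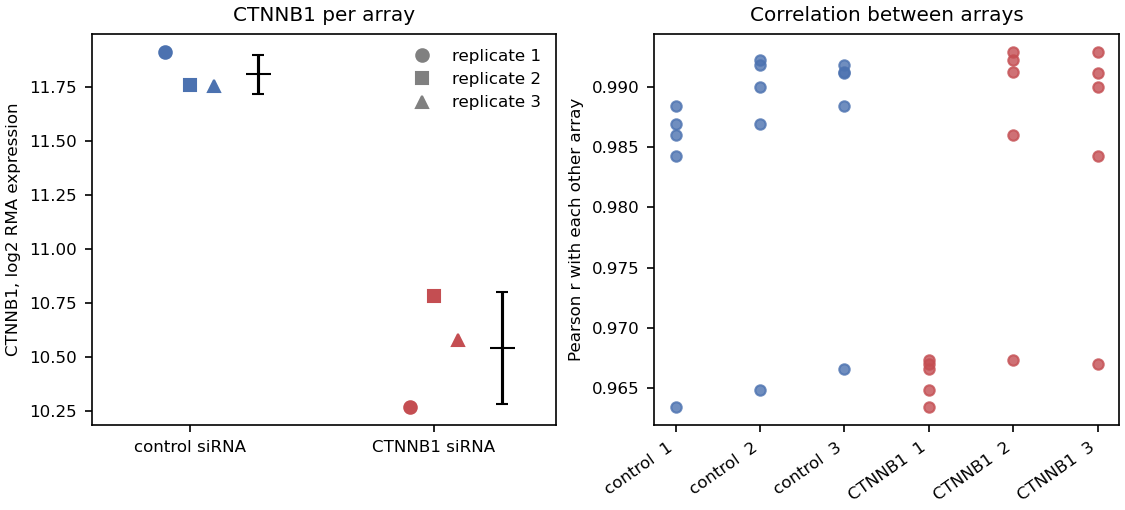
The left panel plots log2 RMA expression of CTNNB1 on each array (points, shaped by replicate) with the group mean ± SD in black; the 3 CTNNB1 siRNA arrays lie between 10.27 and 10.78, below the 3 controls at 11.75 to 11.92. The right panel plots the Pearson correlation of each array with each of the others, across transcript clusters; the points of CTNNB1 siRNA replicate 1 lie between 0.963 and 0.967.

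The next question was which other genes changed when CTNNB1 was silenced. AKR1B10, an aldo-keto reductase that reduces retinal and other carbonyls, rose 7.66-fold, from a mean log2 expression of 3.81 ± 0.44 (SD, n = 3) to 6.75 ± 0.25 (SD, n = 3), a log2 difference of 2.94 (SE 0.24). Its mean over the arrays lay among the dimmest 40% of clusters, where RMA compresses differences, so the size of the fold is uncertain. It was the 1 gene past the threshold in limma (adjusted p = 0.0372), and no gene fell past it. The next 3 genes, named here after their values were seen, each had an adjusted p of 0.0935. They were EMP1, an epithelial membrane protein gene (2.69-fold higher), ARL14, a small GTPase gene (2.30-fold higher), and MUC17, a transmembrane mucin gene of the intestinal surface (3.95-fold higher). ARL14, with a mean of 4.39, was among the dimmest 40% of clusters as well, so its fold is uncertain for the same reason. At an unadjusted p under 0.05 there were 1098 transcript clusters, 592 higher and 506 lower, where 973 would be expected by chance. At an unadjusted p under 0.001 there were 21 higher and 2 lower, where 19.5 in all would be expected by chance. The groups did not overlap for 13.6% of transcript clusters, against 10% by chance, and 224 of these were higher and 212 lower by at least 1.5-fold.

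The log2 difference of AKR1B10 was 2.70 to 3.13 when any 1 array was left out, while its call depended on the arrays kept. Without control siRNA replicate 1, 2 or 3 its adjusted p in limma was 0.550, 0.127 and 0.125, and without CTNNB1 siRNA replicate 2 or 3 it was 0.114 and 0.218. Each of these limma fits called 0 genes, with 695, 905, 768, 1350 and 1099 transcript clusters at an unadjusted p under 0.05. Without CTNNB1 siRNA replicate 1, the array that stood apart, it was 0.0138 and 10 genes were called, all higher. With arrays weighted by their quality, 13 genes were called, 12 higher and CTNNB1 lower (adjusted p = 0.0219). Genes called in either of these fits, named here after their values were seen, included CREB3L3, a transcription factor gene of liver and intestine, with a log2 difference of 1.83 over all 6 arrays. TFF1, a trefoil peptide gene of gastric mucosa, had 1.79, and 1.24 without CTNNB1 siRNA replicate 1, the fit that called it. KRT20, a keratin gene of differentiated intestinal epithelium, had 1.51, a size that is uncertain because the gene was among the dimmest 40%. LGALS4, a galectin gene of the gut epithelium, had 1.52 and PSCA, a surface antigen gene, 0.96. ALPP and ALPG, near-identical alkaline phosphatase genes whose probes are uncertain for that reason, had 1.39 and 1.28.

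**Figure D2:**
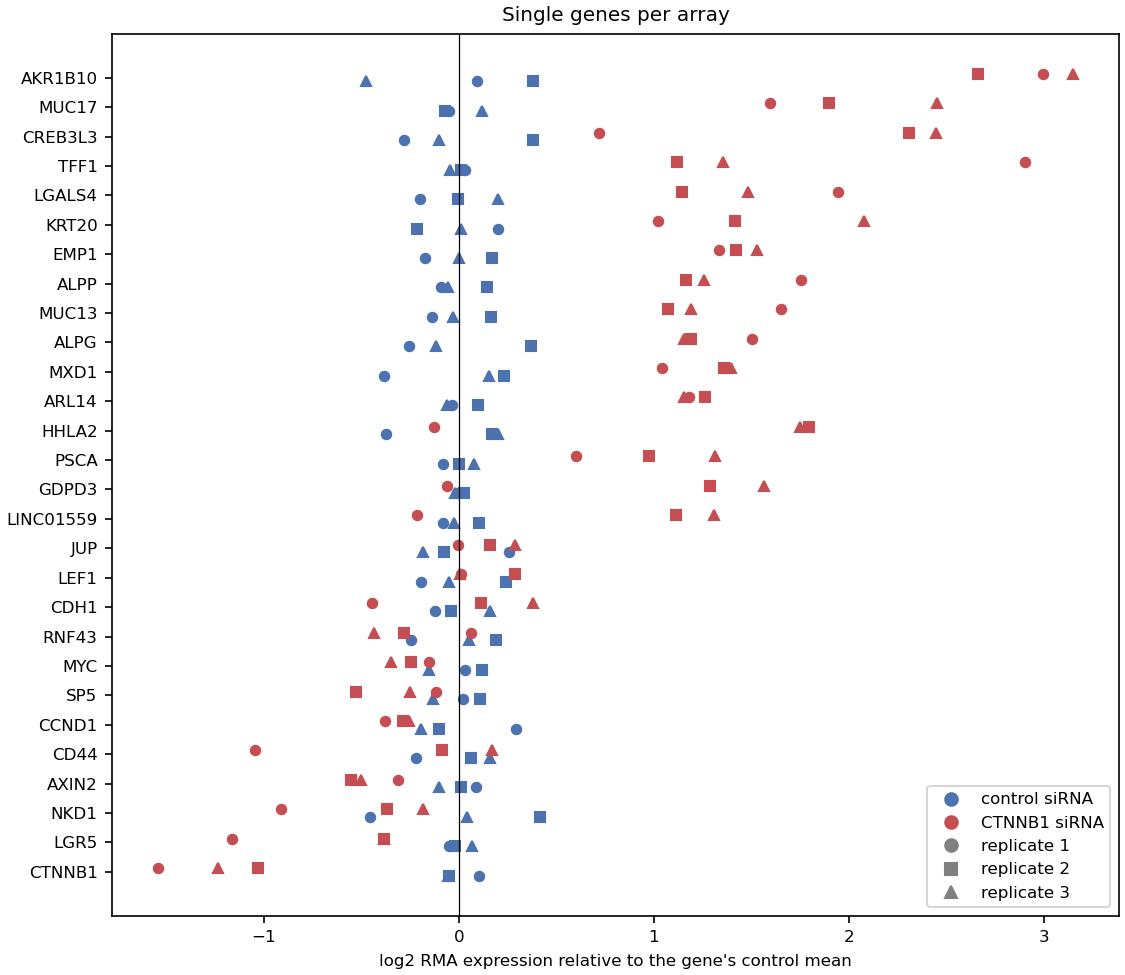
Log2 RMA expression of single genes on each array, relative to the gene's control mean (horizontal axis), for genes called with all arrays weighted equally, with array weights or without CTNNB1 siRNA replicate 1, and for the Wnt pathway and adhesion genes fixed beforehand; each point is an array, blue for control siRNA and red for CTNNB1 siRNA, shaped by replicate. AKR1B10 lies highest, at a mean difference of 2.94, CTNNB1 lies lowest, at -1.27, and in HHLA2, GDPD3 and LINC01559, singled out after their values were seen, CTNNB1 siRNA replicate 1 does not lie above the highest control.

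Among known targets of beta-catenin signalling, AXIN2, a negative feedback gene of the pathway, was 9.27 ± 0.10 (SD, n = 3) in control cells and 8.82 ± 0.13 (SD, n = 3) after CTNNB1 siRNA, a log2 difference of -0.45 (SE 0.14). LGR5, a stem cell receptor gene, differed by -0.64 (SE 0.22), NKD1, a pathway inhibitor, by -0.49 (SE 0.27), CCND1, encoding cyclin D1, by -0.31 (SE 0.16), SP5 by -0.30 (SE 0.16) and MYC by -0.25 (SE 0.14). The groups were fully apart for AXIN2, LGR5 and CCND1, and none of these genes passed limma over all genes (adjusted p = 0.816 each) or among the 12 genes fixed beforehand (0.069 for AXIN2 and 0.0821 for LGR5). CTNNB1, the silenced gene, is 1 of the 12, and its small p lowers the adjusted p of the others. RNF43 differed by -0.22 (SE 0.19), CD44 by -0.32 (SE 0.30), JUP, encoding gamma-catenin, by 0.15 (SE 0.17), LEF1 by 0.10 (SE 0.17) and CDH1, encoding E-cadherin, by 0.016 (SE 0.22). Without CTNNB1 siRNA replicate 1 the difference was 0.044 for CD44, -0.38 for LGR5, -0.27 for NKD1 and -0.36 for RNF43. NKD1 was -0.28 without control siRNA replicate 2, CCND1 -0.16 without control siRNA replicate 1 and SP5 -0.18 without CTNNB1 siRNA replicate 2. Over the fits that leave out 1 array RNF43 lay between -0.36 and -0.11, JUP between 0.057 and 0.28, LEF1 between 0.0056 and 0.22 and CDH1 between -0.16 and 0.25. CD44 was -0.56 without CTNNB1 siRNA replicate 3.

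The list of Wnt target genes shifted lower as a set, with 24 of 37 measured members lower and 13 higher and a median log2 difference of -0.12. The list's mean was -0.12, 0.099 and 0.024 on control siRNA replicates 1 to 3. It was -0.24, -0.087 and -0.074 on CTNNB1 siRNA replicates 1 to 3, so the groups overlapped. Camera in limma gave an adjusted p of 0.0319 with a preset correlation between genes, and the adjusted p = 0.321 with an estimated correlation. No member passed over all genes, and 1 passed when adjusted over the list alone: PLAUR, the urokinase receptor gene, which was higher by 0.90 (SE 0.17) against the direction of the list. The call was lost without control siRNA replicate 2 (adjusted p = 0.240, median -0.058) or replicate 3 (0.0607). It was also lost without CTNNB1 siRNA replicate 1 (0.0515), replicate 2 (0.0548, median -0.062) or replicate 3 (0.0722), and with the dimmest 40% of transcript clusters left out (0.0857). The list of Wnt pathway components, with 51 measured members, had a median of -0.027 (adjusted p = 0.787). FZD3, a receptor gene, differed by -0.37 (SE 0.14) and AMER1 by -0.51 (SE 0.24), and 0 members passed over all genes or adjusted over the list alone. The groups overlapped for AMER1, whose difference was -0.25 without control siRNA replicate 1.

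Of the 33 lists fixed beforehand, 16 passed camera with the preset correlation of 0.01, 10 higher and 6 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.0751). The estimated correlation was below the preset 0.01 for the interferon (-0.0082), epithelial to mesenchymal transition (-0.001) and membrane traffic (-0.0184) lists. These lists lost their calls as well, so the 2 settings of camera differ in more than the correlation. For the other lists that passed, the estimate was 0.0157 to 0.331. A loss with the estimated correlation therefore does not by itself show correlated genes. With fry, a rotation test of whether the genes of a set move on balance one way, 2 passed, the interferon list and the NRF2 list. The preset correlation also called between 0 and 12 lists, with a median of 7, when the 6 arrays were divided into other groups of 3 and 3 that mix both siRNAs, so each list that passed is given below with both p-values.

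Genes of gastric and intestinal epithelial differentiation shifted higher as a set in camera with the preset correlation, with 19 of 33 measured members higher, 14 lower and a median of 0.13 (adjusted p = 0.000884). The call was lost with adjusted p = 0.321 with an estimated correlation and with fry (0.269), and the median was 0.033 without CTNNB1 siRNA replicate 3 (camera adjusted p = 0.0368). LGALS4 was 8.44 ± 0.20 (SD, n = 3) in control cells and 9.97 ± 0.40 (SD, n = 3) after CTNNB1 siRNA, a 2.88-fold difference. MUC13, a transmembrane mucin gene of the gut epithelium, was 9.72 ± 0.15 (SD, n = 3) and 11.02 ± 0.31 (SD, n = 3), a 2.48-fold difference. KRT20 (log2 difference 1.51, SE 0.27), KLF4, a transcription factor gene of differentiated epithelium (1.12, SE 0.22), TFF1 (1.79, SE 0.42) and AGR2, a disulphide isomerase gene of mucus-secreting cells (0.83, SE 0.22), were named after their values were seen. All 4 were higher on every CTNNB1 siRNA array than on any control array. These 6 of 33 measured members passed when adjusted over the list alone, and 0 passed over all genes. Without CTNNB1 siRNA replicate 1 the log2 difference of TFF1 was 1.24. Other gastric genes of the list, chosen after their values were seen, differed little: MUC6 by -0.040, the pepsinogen gene PGC by -0.051, GKN1 by -0.027 and TFF2 by 0.17. MUC6, at 4.96 to 5.31 on the arrays, lay below 5.362, the mean under which clusters were counted as dim. RMA compresses differences there, so its small difference does not show that it was unchanged. The levels of PGC, GKN1 and TFF2 are not given here, so the same may hold for them. SOX2, a foregut transcription factor gene, was 2.30-fold lower and did not pass (0.0629 when adjusted over the list alone); its log2 difference was -1.20, and -0.74 without control siRNA replicate 1.

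Interferon response genes also shifted higher, with 32 of 37 measured members higher, 5 lower and a median log2 difference of 0.29. The camera adjusted p was 9.34e-08, with adjusted p = 0.0751 with an estimated correlation and 0.0138 by fry. OAS1, an antiviral oligoadenylate synthetase gene, was 8.76 ± 0.14 (SD, n = 3) in control cells and 9.54 ± 0.35 (SD, n = 3) after CTNNB1 siRNA. DDX60, a helicase gene of the antiviral response, was 7.60 ± 0.50 (SD, n = 3) and 8.58 ± 0.18 (SD, n = 3). No member passed over all genes or adjusted over the list alone, where both had 0.0821. The list's mean lay 0.28 to 0.36 above the control mean on the 3 CTNNB1 siRNA arrays and between -0.050 and 0.038 on the controls. MHC class I and antigen presentation genes shifted higher with a median of 0.29 over 12 measured members (camera adjusted p = 0.00386; adjusted p = 0.321 with an estimated correlation). B2M, the MHC class I light chain gene, differed by 0.60 (SE 0.24) and the immunoproteasome gene PSMB9 by 0.60 (SE 0.28), and 0 members passed over all genes or adjusted over the list alone. Without CTNNB1 siRNA replicate 1 these differences were 0.33 and 0.25. The mean of this list was 0.62 on CTNNB1 siRNA replicate 1 and 0.13 and 0.15 on replicates 2 and 3, and its median was 0.16 without that replicate (adjusted p = 0.0328) and 0.19 without control siRNA replicate 1 (0.0148).

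Genes of DNA replication shifted lower as a set in camera with the preset correlation (adjusted p = 2.64e-07): 40 of 46 measured G1/S members were lower, 6 higher, with a median log2 difference of -0.26. The call was lost with adjusted p = 0.321 with an estimated correlation and with fry (0.315). The list's mean was 0.21, -0.18 and -0.029 on control siRNA replicates 1 to 3 and -0.089, -0.36 and -0.34 on CTNNB1 siRNA replicates 1 to 3, so the groups overlapped, and another division of the 6 arrays into 3 and 3 gave this list a smaller camera p. POLD3, a DNA polymerase delta subunit gene, went from 7.67 ± 0.14 (SD, n = 3) to 7.15 ± 0.065 (SD, n = 3), and DTL, which directs replication licensing factors to degradation, from 9.39 ± 0.18 (SD, n = 3) to 8.64 ± 0.38 (SD, n = 3). No member passed over all genes or adjusted over the list alone (both 0.181). Mitotic genes had a median of -0.099 over 45 members (camera adjusted p = 0.00337; adjusted p = 0.454 with an estimated correlation), with FOXM1, a mitotic transcription factor gene, at -0.54 (SE 0.19; -0.35 without CTNNB1 siRNA replicate 1) and CDCA8 at -0.36 (SE 0.14). This call was lost without control siRNA replicate 2 (adjusted p = 0.0862) and CTNNB1 siRNA replicate 3 (0.227, median -0.054), and the median was -0.25 without control siRNA replicate 1 and -0.15 without CTNNB1 siRNA replicate 2. The mean of the mitotic list was -0.17, 0.10 and 0.071 on control siRNA replicates 1 to 3. It was -0.15, -0.042 and -0.24 on CTNNB1 siRNA replicates 1 to 3, so the groups overlapped. Replication-dependent histone genes had a median of -0.25 over 25 members (camera adjusted p = 0.0013; adjusted p = 0.321 with an estimated correlation), with H3C2 at -0.44 (SE 0.16) and H3C7 at -0.73 (SE 0.30). The groups overlapped for H3C7, whose difference was -0.45 without control siRNA replicate 1. The histone call was lost without control siRNA replicate 1 (adjusted p = 0.0716, median -0.16). In neither of these lists did a member pass over all genes or adjusted over the list alone.

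MYC targets and ribosome biogenesis genes had a median of -0.24, with 28 of 35 measured members lower (camera adjusted p = 0.0016; adjusted p = 0.58 with an estimated correlation). UTP20, a small ribosomal subunit assembly gene, differed by -0.67 (SE 0.25), and by -0.37 without control siRNA replicate 1. The list's mean was 0.27, -0.16 and -0.11 on control siRNA replicates 1 to 3. It was 0.084, -0.35 and -0.27 on CTNNB1 siRNA replicates 1 to 3, so the groups overlapped. No member passed over all genes, and the member that passed when adjusted over the list alone was MXD1, which encodes an antagonist of MYC and was 2.41-fold higher. The call was lost without control siRNA replicate 1 (adjusted p = 0.273, median -0.054), CTNNB1 siRNA replicate 2 (0.165, median -0.12) or replicate 3 (0.0722), and without CTNNB1 siRNA replicate 1 the median was -0.37. Genes of the small RNA machinery had a median of -0.31 over 15 members (camera adjusted p = 0.00437; adjusted p = 0.321 with an estimated correlation), with XPO5, the microRNA precursor exporter gene, at -0.38 (SE 0.14) and the nuclease gene DROSHA at -0.40 (SE 0.20; -0.21 without CTNNB1 siRNA replicate 1). In this list 0 members passed over all genes or adjusted over the list alone. Without control siRNA replicate 1 that call was lost (adjusted p = 0.0699, median -0.20), as it was without the arrays numbered 1 of both groups (0.190, median -0.074), and without CTNNB1 siRNA replicate 1 the median was -0.19.

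Genes of the NRF2 and oxidative stress list shifted higher, with 17 of 21 measured members higher, a median of 0.24 and a mean of 0.44. The camera adjusted p was 1.32e-05, with adjusted p = 0.206 with an estimated correlation and 0.0396 by fry. AKR1B10 passed over all genes and was the 1 member that passed when adjusted over the list alone. Other members chosen after their values were seen were AKR1C3 at 1.07 (SE 0.30), AKR1C1 at 1.02 (SE 0.36) and NQO1, a quinone reductase gene, at 0.058 (SE 0.19). Without CTNNB1 siRNA replicate 1 AKR1C1 was at 0.56. AKR1B10, AKR1C1 and AKR1C3 were among the dimmest 40% of clusters, so the sizes of their differences are uncertain. The mean of the list was 0.61 on CTNNB1 siRNA replicate 1 and 0.32 and 0.38 on replicates 2 and 3, and without replicate 1 its median was 0.12.

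Glycolysis and hypoxia genes had a median of 0.19 with 23 of 31 measured members higher (camera adjusted p = 0.000159; adjusted p = 0.321 with an estimated correlation). ANKRD37, a hypoxia-inducible gene, was 1.88-fold higher and passed when adjusted over the list alone, and NDRG1, a stress-responsive gene, was 1.98-fold higher and did not (0.0557). The median was 0.12 without control siRNA replicate 3 and 0.086 without CTNNB1 siRNA replicate 1, and another division of the arrays gave a smaller camera p here too. ERK feedback and immediate early genes had a median of 0.20 over 30 members (camera adjusted p = 0.00082; adjusted p = 0.445 with an estimated correlation). DUSP1, a MAP kinase phosphatase gene, was 2.71-fold higher and was the 1 member that passed when adjusted over the list alone, and EPHA2, a receptor kinase gene, was 1.65-fold higher. The ERK call was lost without control siRNA replicate 1 (adjusted p = 0.317, median 0.092), whose mean for the list was -0.41 against 0.20 and 0.21 on the other controls and 0.25 to 0.31 on the CTNNB1 siRNA arrays. It was also lost without the arrays numbered 1 of both groups (adjusted p = 0.190, median 0.10). No member of the glycolysis or ERK lists passed over all genes.

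The remaining lists past the threshold shifted higher. The epithelial to mesenchymal transition list, which holds genes of both cell states, had a median of 0.12 over 35 members (camera adjusted p = 0.0171; adjusted p = 0.321 with an estimated correlation). The members with the smallest p were epithelial: MUC1, an epithelial surface mucin, was 1.76-fold higher and passed when adjusted over the list alone, and CLDN4, a tight junction gene, was 1.59-fold higher. The log2 difference of CLDN4 was 0.67, and 0.42 without CTNNB1 siRNA replicate 1. That call was lost without control siRNA replicate 3 (adjusted p = 0.0682, median 0.048) or CTNNB1 siRNA replicate 3 (0.0536), and the median was 0.075 without control siRNA replicate 1 and 0.061 without CTNNB1 siRNA replicate 1. Integrin and extracellular matrix genes had a median of 0.13 over 31 members (camera adjusted p = 0.00386; adjusted p = 0.321 with an estimated correlation), with LAMB3, a laminin gene of epithelial basement membrane, at 0.61 (SE 0.13) and CD9 at 0.53 (SE 0.17). Their call was lost without control siRNA replicate 1 (0.0522). Apoptosis regulators had a median of 0.18 over 25 members (camera adjusted p = 0.0103; adjusted p = 0.321 with an estimated correlation), with the anti-apoptotic genes MCL1 at 0.72 (SE 0.24) and XIAP at 0.39 (SE 0.16). The mean of this list was 0.32 on CTNNB1 siRNA replicate 1 and 0.10 on replicates 2 and 3, and the call was lost without replicate 1 (adjusted p = 0.163, median 0.11). It was also lost with array weights (0.0786, median 0.093) and without the arrays numbered 1 of both groups (0.171, median 0.041). Membrane traffic and lysosome genes had a median of 0.14 over 22 members (camera adjusted p = 0.0171; adjusted p = 0.321 with an estimated correlation), with the protease gene CTSB at 0.38 (SE 0.16) and SQSTM1, an autophagy receptor gene, at 0.48 (SE 0.24). The groups overlapped for SQSTM1, and without CTNNB1 siRNA replicate 1 the differences were 0.25 for both genes. They lost the call without control siRNA replicate 1 (0.0680, median 0.076), CTNNB1 siRNA replicate 2 (0.0688) or replicate 3 (0.0536). In these 4 lists 0 members passed over all genes, and MUC1 was the 1 member that passed when adjusted over its list alone.

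The other 17 lists did not pass with all 6 arrays weighted equally, normalised as deposited and without a block. Unfolded protein and integrated stress response genes had a median of 0.16 (adjusted p = 0.0541), and their mean was 0.47 on CTNNB1 siRNA replicate 1 against 0.043 and 0.034 on replicates 2 and 3. The list passed without control siRNA replicate 2, control siRNA replicate 3 or CTNNB1 siRNA replicate 3 (smallest adjusted p = 0.00844, where it was adjusted p = 0.534 with an estimated correlation). It also passed with all arrays after centring (adjusted p = 0.0498) and with the replicate block (0.0431), and without either it had adjusted p = 0.58 with an estimated correlation. Its median was 0.033 without CTNNB1 siRNA replicate 1. With an estimated correlation 0 of the 33 lists passed in any of the 6 fits that leave out 1 array (smallest adjusted p = 0.180). NF-kB and inflammatory genes had a median of 0.10 (adjusted p = 0.0738), with the chemokine gene CCL5 at 0.55 (SE 0.17) and the cyclooxygenase gene PTGS2 at -0.77 (SE 0.28; -0.45 without CTNNB1 siRNA replicate 1). This list passed without CTNNB1 siRNA replicate 1 (median 0.24, adjusted p = 0.000238; adjusted p = 0.221 with an estimated correlation). It also passed with array weights (median 0.17, adjusted p = 0.00188) and without the arrays numbered 1 of both groups (median 0.21, 0.00163), and with equal weights it had adjusted p = 0.58 with an estimated correlation. TGF-beta and BMP targets had a median of 0.063 (adjusted p = 0.303), with ID1 at 0.39 (SE 0.14). The median and adjusted p were 0.052 and 0.649 for cholesterol synthesis genes, 0.021 and 0.735 for YAP/TEAD targets and -0.052 and 0.787 for stem cell and progenitor markers. They were 0.0089 and 0.883 for fatty acid and lipid synthesis genes and 0.0043 and 0.863 for oxidative phosphorylation genes. KLF2 at 0.70 (SE 0.18) and CD24 at 0.66 (SE 0.20) had the smallest p among the stem cell markers. In the fatty acid and lipid list GPAM, a glycerolipid synthesis gene, differed by -0.84 (SE 0.26). AGPAT2 of the same list differed by 0.73 (SE 0.24), and by 0.47 without CTNNB1 siRNA replicate 1. Cholesterol synthesis genes passed without control siRNA replicate 1 (adjusted p = 0.0448, median 0.11; adjusted p = 0.607 with an estimated correlation), and cytosolic ribosomal protein genes passed lower without CTNNB1 siRNA replicate 1 (0.0067, median -0.10; adjusted p = 0.653 with an estimated correlation).

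In several lists the median and the direction of the test differed in sign, with medians near 0. The median was below 0 and the test direction higher for p53 targets (-0.0011, adjusted p = 0.318), reference genes (-0.028, 0.863) and the Notch pathway (-0.0031, 0.924). The same held for adherens junction and desmosome genes (-0.019, 0.924) and heat shock and proteotoxic stress genes (-0.054, 0.945), and the reverse for cytosolic ribosomal proteins (0.031, 0.794). In the heat shock list HMOX1, the heme oxygenase gene, was 1.94-fold higher and passed when adjusted over the list alone; in the p53 list PLK3 differed by 0.50 (SE 0.16). Markers of other cell types did not pass: immune cell markers had a median of -0.079 (adjusted p = 0.787) and fibroblast and endothelial markers 0.032 (0.525). In the 17 lists that did not pass, 0 members passed over all genes, and HMOX1 was the 1 member that passed when adjusted over its list alone.

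**Figure D3:**
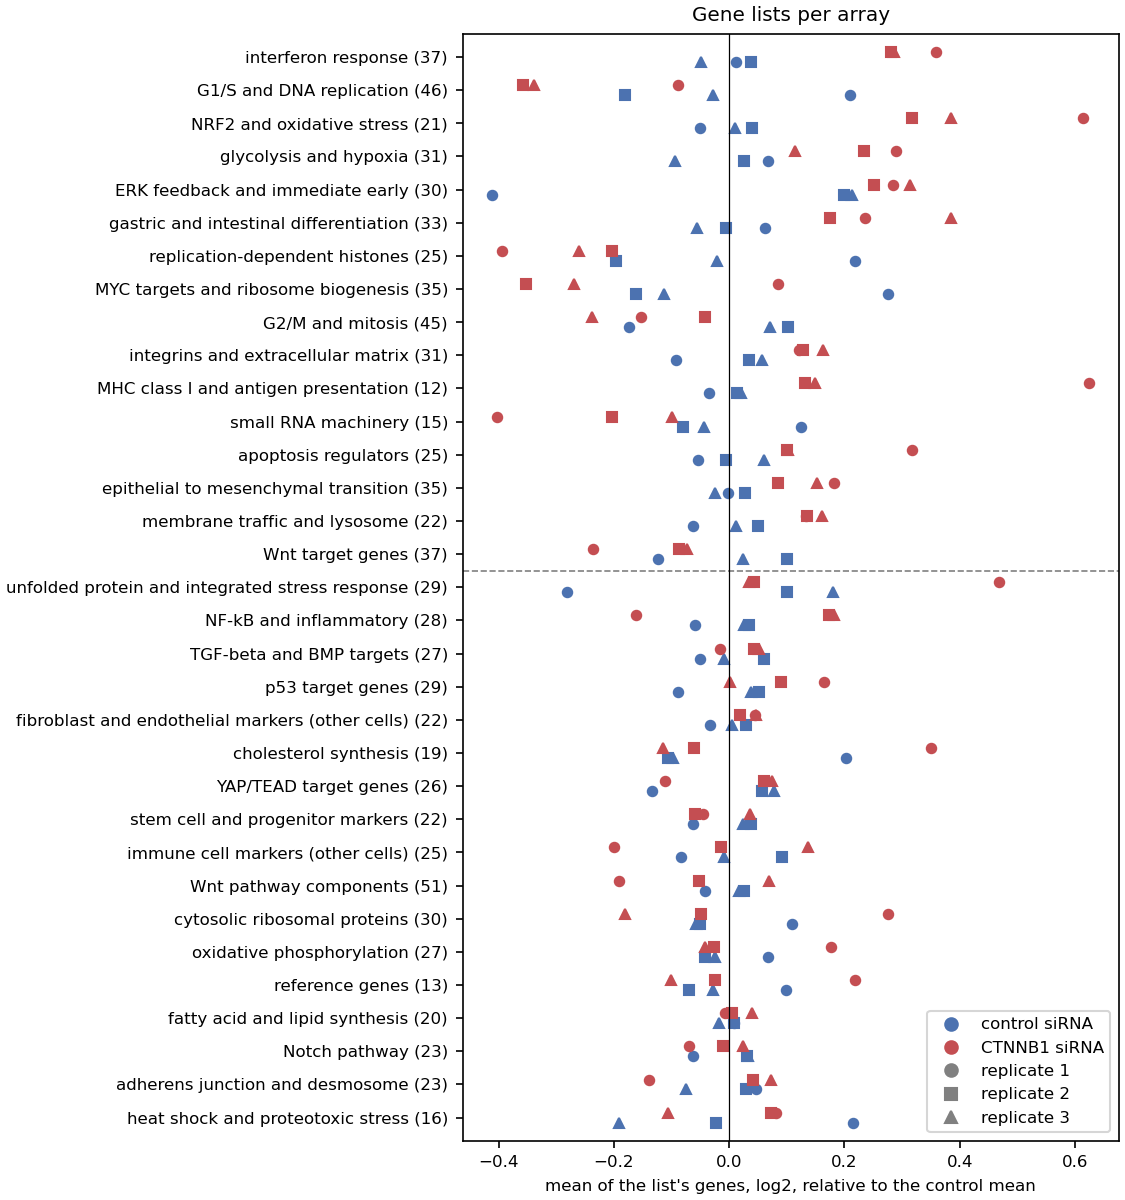
Mean log2 expression of each gene list on each array, relative to the control mean (horizontal axis), with the number of measured members in brackets; each point is an array, blue for control siRNA and red for CTNNB1 siRNA, shaped by replicate, and the dashed line separates the 16 lists with a camera adjusted p under 0.05 (above) from the other 17. The interferon list lies at 0.28 to 0.36 on the CTNNB1 siRNA arrays and at -0.050 to 0.038 on the controls, while the MHC class I list reaches 0.62 on CTNNB1 siRNA replicate 1 alone.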

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

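Leaving out the arrays numbered 1 of both groups together, the estimated correlation with 1 array left out, and 1 array left out for the mucin and CEACAM families, were chosen after the data were seen; the other alternatives were planned. The count of 1 changed gene in limma was the same after quantile normalisation or centring, with an intensity trend and robust eBayes, with 1 cluster per gene, with a fold minimum of 1.5 and with treat. It was 13 with array weights (12 higher, 1 lower), 2 (both higher) without the arrays numbered 1, and 0 with dim clusters left out (which removes AKR1B10 itself), with all clusters tested, at an adjusted p of 0.01 and with the replicate block, where 670, 1569, 1098 and 1123 clusters had an unadjusted p under 0.05. The adjusted p of AKR1B10 ranged from 0.00402 to 0.550. Leaving out 1 array at a time gave 0 to 10 changed genes and 0 to 10 higher. The simulation found 51.6% of changes of 1 on the log2 scale with 100 clusters changed by each size, a share that need not hold for the real arrays. Signal near background limits the dim clusters. Of clusters at an unadjusted p under 0.05, 53.9% were higher, 59.2% after quantile normalisation and 47.3% after centring.

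CTNNB1 was lower under every alternative, by -1.39 to -1.08 on the log2 scale, and its adjusted p ranged from 0.0219 to 0.937; it passed with array weights (-1.12), where CTNNB1 siRNA replicate 1 had a weight of 0.226 against 0.720 to 1.87 for the others. The number of lists past the threshold was 11 to 17 in the fits with the preset correlation, 0 with the estimated correlation, with all arrays or with any 1 left out, and 2 with fry. The Wnt target list lost its call with dim clusters left out (median -0.12, adjusted p = 0.0857), with the estimated correlation (median -0.12, 0.321) and with fry (0.364). It also lost it without any 1 array but control siRNA replicate 1 (medians of -0.13 to -0.058 where the call was lost, against -0.16 to -0.058 over all leave-outs). Its adjusted p was 0.00184 to 0.240 over the 15 fits with the preset correlation. The differentiation list, with a median of 0.13, lost its call with the estimated correlation (0.321) and fry (0.269), and had 2.00e-07 to 0.0368 over the other 15. With the estimated correlation and control siRNA replicate 1, 2 or 3 or CTNNB1 siRNA replicate 1, 2 or 3 left out, its medians were 0.11, 0.12, 0.10, 0.14, 0.11 and 0.033 (adjusted p 0.360 to 0.536). Those of the Wnt target list were -0.16, -0.058, -0.13, -0.10, -0.062 and -0.12 (0.536 at most). The cause of these losses was not tested. Over 13 alternative fits, 86 genes were followed and 2 of them, CDH1 and CD44, changed sign 5 times in all, never past the threshold. The lists for interferon response, G1/S, NRF2, glycolysis, gastric and intestinal differentiation and MHC class I kept their call in all 15 fits other than the estimated correlation and fry. For MHC class I this held narrowly: over these fits its median was 0.10 to 0.34 and its camera adjusted p 0.00252 to 0.0497.

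The labels do not say that equal replicate numbers share a day or passage, so the number served as a block only among the alternatives. Deviations of same-numbered arrays from their group means correlated at 0.0922, 0.120 and 0.0980 across clusters. Every array correlated best with its own number, a hint of pairing from the data and not the design. For the Wnt target, G1/S and MYC lists, whose groups overlapped, each CTNNB1 siRNA array had a lower list mean than the control of its number. The mitotic list, which overlapped too, was lower for numbers 2 and 3 and higher for number 1 (-0.15 against -0.17). With the number as a block, 0 genes passed, AKR1B10 had an adjusted p of 0.363, CTNNB1 kept -1.27 (0.646) and 17 lists passed, 16 of them among those called without the block and the other the unfolded protein and integrated stress response list (median 0.16, adjusted p = 0.0431).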

Other observations

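The tests of the array that stood apart, of the differentiation and interferon lists and of the mucin and CEACAM families were chosen after the results were seen, and the divisions of the arrays into other groups were planned.

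CEACAM5 and CEACAM6, adhesion molecule genes of the gut epithelium chosen after their values were seen, were 2.55-fold and 2.27-fold higher after CTNNB1 siRNA, with log2 differences of 1.35 (SE 0.36) and 1.18 (SE 0.30). Both lay higher on each CTNNB1 siRNA array than on any control array, and neither passed limma over all genes (adjusted p = 0.816). The hypothesis that CEACAM genes were higher as a class stayed undecided: the other 9 members had a median of 0.22 and a camera p of 0.0825 (0.479 with the estimated correlation). Their median was -0.056 and 0.054 without control siRNA replicate 1 or 2, and 0.079 and 0.0056 without CTNNB1 siRNA replicate 2 or 3. The camera p was 0.0258 without control siRNA replicate 3 and 0.000898 without CTNNB1 siRNA replicate 1 (0.387 and 0.222 with the estimated correlation). The hypothesis that mucin genes were higher as a class met its criterion, a camera p under 0.05 with the preset correlation. It was left open too, because the p missed 0.05 with the estimated correlation and without some arrays. The 15 mucin genes other than MUC13 and MUC17 had a median of 0.13, against 1.64 for that pair, with a camera p of 0.0128 (0.359 with the estimated correlation). This p was 0.0656 without CTNNB1 siRNA replicate 2 (median 0.072) and 0.396 without replicate 3 (median -0.039). The median was 0.043 without control siRNA replicate 1 and 0.21 without control siRNA replicate 2. Without CTNNB1 siRNA replicate 1 the median was 0.18 and the camera p 9.13e-06 (0.114 with the estimated correlation). With all 6 arrays the medians were 0.11 and 0.12 for the mucins and 0.21 for the CEACAM genes after quantile normalisation and after centring. MUC1 (0.82) and MUC20 (0.54, chosen after its values were seen) were the 2 higher at an unadjusted p under 0.05, while MUC2 (0.13), MUC6 (-0.040) and MUC16 (-0.14) showed smaller differences. MUC2, MUC6 and MUC16 were dim on every array, where RMA compresses differences, so these values do not show absence of change. The criteria for the CEACAM, mucin and interferon gene tests were tightened after a first look, because a p that misses the threshold in so few or such dim genes does not exclude a 1.5-fold change; under the first criteria the CEACAM class and the induction of an interferon gene would have counted as excluded.

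CTNNB1 siRNA replicate 1 deviated from the mean of its 2 group partners with an SD of 0.547 on the log2 scale, against 0.252 to 0.336 for the other arrays, and 7.72% of clusters lay at least 2-fold away. A stronger response to the same siRNA is argued against as the whole cause, since the array's deviations did not follow the response of its partners across clusters (r = -0.0244 and -0.0674). For scale, the responses of CTNNB1 siRNA replicates 2 and 3, each over a different control array, correlated at 0.171. A control array under the wrong label is argued against as well, since CTNNB1 on CTNNB1 siRNA replicate 1 differed by -1.49 from the lowest control. Small nuclear and nucleolar RNAs were at least 2-fold lower in 18.4% of their 239 clusters against 3.79% of others. Without them the SD was 0.535. These 239 of the 19460 tested clusters are too few to change the SD much, so it cannot decide whether the yield of small RNAs differed. The median deviation of the small RNA clusters from the group partners was -0.11 on this array, within the range of -0.22 to 0.24 on the other arrays. RNA quality, labelling or hybridisation of this sample may account for the deviation, which grew with signal from 0.281 to 0.749 over 5 bins of mean level, and this was not tested.

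The higher level of the gastric and intestinal differentiation list was not confined to CTNNB1 siRNA replicate 1: without that array its median was 0.14 against 0.13 with it, and its camera adjusted p was 1.54e-06 with the preset correlation, with adjusted p = 0.442 with an estimated correlation. It depended more on CTNNB1 siRNA replicate 3, without which the median was 0.033: the median member lay at -0.037, 0.044 and 0.22 on replicates 1 to 3, against -0.034 to 0.013 on the controls. Among the 10 divisions of the arrays into 3 and 3, the real one gave the smallest camera p for this list (0.000161, against 0.00492 for the next). Loss of beta-catenin and an effect of the siRNA on other transcripts cannot be told apart, because 1 CTNNB1 siRNA reagent was in the design, with no rescue.

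The interferon response list had a median of 0.29 with and without CTNNB1 siRNA replicate 1, so that array alone is argued against. Without it the camera adjusted p was 2.04e-09 with the preset correlation, with adjusted p = 0.221 with an estimated correlation. Its camera p was 2.83e-09 in the real division of the arrays and 0.00168 in the next. Of 16 interferon genes measured, 0 were higher at an unadjusted p under 0.05 in limma, and IFNB1 was lower by this measure (-0.47); only IFNL1, IFNL2 and IFNL3 lay above the dimmest 40% of clusters, so induction of an interferon gene remains possible and undecided. A difference between the siRNA duplexes in sensing by the cell could also give this pattern and was not tested.

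For the number of changed genes, 1 of the 10 divisions of the arrays, the real one, reached 1 gene, and the highest of the others was 0. At an unadjusted p under 0.05 in limma, another division gave 1154 clusters, against 1098 in the real one. For the gene lists, 1 of the 10 divisions, the real one, reached 16 lists, and the highest of the others was 12. With 10 divisions the share cannot fall under 0.05. G1/S genes had a smaller camera p in another division (2.46e-15 against 1.60e-08), as did glycolysis genes (1.34e-06 against 1.93e-05). The 13837 transcript clusters with no gene or several genes, tested on their own with limma, gave 0 past an adjusted p of 0.05 (smallest 0.552) and 534 at an unadjusted p under 0.05.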
